A study of Mus musculus with 6 samples.

How the data were processed

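The samples were 6 RNA-seq libraries from mouse embryonic fibroblasts of the C57BL/6 strain at passages 5 to 7. Cells received phosphate-buffered saline (control), TNF-α with cycloheximide (TC), or TNF-α with cycloheximide and z-VAD-fmk (TCZ), with 2 libraries per group. TNF-α is an inflammatory cytokine, cycloheximide blocks translation, and z-VAD-fmk is a broad caspase inhibitor. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected on Dynabeads, fragmented and reverse transcribed with random primers, and libraries were sequenced on an Illumina HiSeq 2000. Doses and treatment times are not given in the sources used here. TNF-α and cycloheximide were always given together, so their separate contributions cannot be told apart.

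The authors deposited one table with raw counts of reads per gene and RPKM values for each library, per the file headers. The deposited counts were whole numbers summing to between 24922627 and 52909926 per library. Per the submitters' processing notes, bcl2fastq, HISAT2 2.1.0 and HTSeq were used with build mm10. The strand setting, annotation version, read pairing and any filter are not given in the sources used here. Reads from overlapping genes, and from a gene and its antisense partner, were therefore treated as uncertain. The authors' RPKM values equalled the counts divided by the table's gene length in kilobases and scaled to the library total, with a largest difference of 5e-07 from recomputed values. RPKM was used only for that check. Of the table's gene symbols, 36837 matched a gene of the GRCm38.p6 annotation. Of these, 99.89% lay on the same chromosome and 57.6% had the same start and end. Coordinates are given as in the deposited table, on mm10.

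Counts were analysed in R 4.3.3 with edgeR 4.0.16. The table held 48897 genes, and 18563 passed the low-count filter (filterByExpr by group, minimum count 10). TMM factors scaled the library totals. All 6 libraries entered one model with group as the only factor, which left 3 residual degrees of freedom. Each of the 3 comparisons was tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Adjusted p-values of genes are from this test. Levels are CPM (counts per 1e6) scaled by TMM, as mean ± SD of the 2 libraries of a group, and log2 fold changes carry their standard error (SE). A fold against a group with no count was computed against 3 counts over the group. Counting intervals of ratios and such floors cover counting error only. The 95% intervals of list medians were read from the ranked values of the list's members. They treat the genes of a list as independent and do not cover the spread between libraries. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

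Before the data were examined, 28 gene lists with 791 members were fixed, of which 789 were in the table; some lists share members, such as 6 genes of the NF-kB list that are also in the necroptosis list. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the data. Adjusted p-values of lists are camera's, adjusted over the lists of a comparison. With the preset correlation 41 list calls passed, and with an estimated correlation 0 of these 41 held, so each call rests on the preset value. fry, which asks whether a list's genes move on balance one way, was also computed for each list. Before the data were examined, a rule also fixed the genes to be named. These were the 5 largest rises and 5 largest falls per comparison among passing genes with a mean of at least 10 CPM, a full symbol of a protein-coding gene and no overlap between the libraries of both groups; the 2 members with the smallest adjusted p from each of the 8 lists with the smallest camera p; and Tnfrsf1a, Ripk1, Ripk3, Mlkl, Casp8, Fadd and Cflar. The rule gave 30, 32 and 32 genes. Further genes are named as members of lists or by themselves, and were chosen after their values were seen.

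Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE size factors, library totals with no further scaling, no low-count filter, a filter of 50 counts in 2 libraries, a model of only the 2 groups compared, the replicate number as a block, leaving out each library in turn, and a change of at least 1 on the log2 scale. A batch term for control 2 and TCZ 2, leaving out both of these libraries, and thinning all libraries to equal depth were added after the data were seen. With library totals alone, the median of all genes moved by -0.14, -0.20 and -0.06 on the log2 scale in TC against control, TCZ against control and TCZ against TC. All fold changes are therefore relative to the TMM scale. To judge calls shared by comparisons with the same control libraries, 20 unchanged groups were simulated.

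The procedure was tested on simulated counts for the 18563 genes. In the simulated TC group 100 genes were changed by 1 and 100 by 2 on the log2 scale, evenly up and down. In the real comparisons most genes passed, so the false calls given here do not measure the error there. In the simulated TC against control, 66% of genes changed by 1 on the log2 scale and 87% of those changed by 2 were recovered, with 14 false calls. For TCZ against TC the shares were 66% and 87%, with 15 false calls, and in the unchanged TCZ against control 1 gene was called. In the list test the 1 raised list passed and 0 of 20 unchanged lists did. Simulated genes were drawn independently of each other. The list test was therefore not tried on lists of correlated genes. Figures were drawn with matplotlib 3.10.9.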

Results

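Poly(A)-selected RNA was measured by sequencing in mouse embryonic fibroblasts after treatments that the series title ties to apoptosis and necroptosis. The 3 groups were saline control, TC and TCZ, with 2 libraries each. Total counts were 46509236 and 26834352 in control, 49560566 and 50854810 in TC, and 52909926 and 24922627 in TCZ. The number of genes with a count was 22489 and 22615 in control, 25593 and 25122 in TC, and 25916 and 25245 in TCZ. The libraries of each group differed beyond counting noise, with a chi-square per gene of 4.64 in control, 5.48 in TC and 7.87 in TCZ. Their log2 levels correlated across genes at 0.998, 0.998 and 0.996 (genes are not independent replicates). The first principal component held 61.9% and the second 28% of the variance, and the biological coefficient of variation was 7.38%.

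Control 2 and TCZ 2 stood apart from the other 4 libraries in depth and in small RNAs. Rnu1a1, a spliceosomal U1 RNA, had 165 counts in control 1 and 3 in control 2, 242 and 274 in TC, and 231 in TCZ 1 against 1 in TCZ 2. Rn7s1, a signal recognition particle RNA, had 4916 and 1338 counts in control, 5704 and 6106 in TC, and 5789 and 4 in TCZ. Values without control 2 and TCZ 2 are therefore given beside the main results, where the lone control and TCZ libraries are assumed to vary like the TC pair. The set of control 2 and TCZ 2 holds no TC library and 1 library of each other group, which is too few for a comparison of its own.

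TC was compared with control to ask what TNF-α with cycloheximide changed. NF-kB feedback genes, cytokines, immediate early genes, interferon-stimulated genes and replication-dependent histone transcripts rose. Tnfaip3, which encodes the NF-kB inhibitor A20 (chromosome 10, 19000910 to 19015410, minus strand), rose from 5.82 ± 0.11 to 492 ± 9.27 CPM (SD, n = 2). Genes of cholesterol synthesis and endoplasmic reticulum (ER) chaperones fell, with Insig1, a sterol-sensing ER protein (chromosome 5, 28071412 to 28078662, plus strand), going from 104 ± 4.93 to 12.5 ± 0.45 CPM. In all, 11264 of 18563 genes passed, 5856 higher and 5408 lower, and at least 2-fold changes numbered 3259 and 2179. The split turned to 5080 higher and 6586 lower with library totals alone. When control 2 and TCZ 2 were left out, 10625 genes passed, of which 10053 were among the 11264.

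Of the 25 NF-kB feedback and survival genes tested, 23 rose and 1 fell, with a median log2 fold change of 1.96 (camera adjusted p = 6.98e-42, and adjusted p = 0.112 with an estimated correlation). Besides Tnfaip3 (log2 6.40 ± 0.10 SE, adjusted p = 1.94e-21), Gadd45b, a stress-response gene, rose by 4.98 ± 0.09 (adjusted p = 1.37e-20). Traf1, a TNF receptor adaptor, had 8 counts in control, all in control 2, against 8609 in TC. Its log2 fold change was 9.70 ± 0.25, 8.35 without control 1 and 14.91 without control 2. Of 29 cytokines, chemokines and adhesion molecules, 26 rose and 0 fell, with a median of 4.73, or 4.12 with 2 genes at their bound (adjusted p = 2.03e-54, and adjusted p = 0.112 with an estimated correlation). Csf2, the growth factor GM-CSF (chromosome 11, 54247270 to 54249899, minus strand), had 0 control counts and was at least 1328-fold higher at 50.6 ± 0.96 CPM. Lif, a cytokine of the interleukin-6 family, rose by 6.57 ± 0.11, the chemokine genes Cxcl2 and Ccl20 by 9.70 ± 0.22 and 9.17 ± 0.25, and Cxcl10 by 8.22 ± 0.14. Fcgr1, an Fc receptor gene, had 2 control counts and a ratio of 934 with a counting interval of 258 to 7720. Both counts lay in control 1, so its log2 value of 9.71 ± 0.25 became 12.90 without control 1 and 9.07 without control 2. That of Ccl20 was 8.55 and 9.76 in these settings.

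Among 40 immediate early genes, the fast targets of growth and stress signals, 38 rose and 1 fell, with a median of 2.13 (adjusted p = 1.33e-63, and adjusted p = 0.197 with an estimated correlation). Atf3, a stress transcription factor, rose by 6.66 ± 0.11 to 242 ± 5.91 CPM. All 42 interferon-stimulated genes tested rose, with a median of 2.88 (adjusted p = 5.23e-26, and adjusted p = 0.112 with an estimated correlation). Ifit1, an antiviral RNA-binding protein gene with close paralogs that may share reads, rose by 5.15 ± 0.14, from 1.12 ± 0.17 to 40.4 ± 1.52 CPM. All 20 replication-dependent histone genes tested rose, with a median of 3.83 (adjusted p = 1.21e-20, and adjusted p = 0.2 with an estimated correlation). Hist1h2bc rose by 3.64 ± 0.09 and the linker histone gene Hist1h1a by 8.13 ± 0.20; near-identical histone copies make values of single histone genes uncertain. The medians without control 2 and TCZ 2 were 1.98 for the NF-kB list, 4.70 for cytokines, 2.07 for immediate early genes, 2.77 for interferon-stimulated genes and 3.74 for histones.

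Cholesterol synthesis and uptake genes fell in 20 of 25 cases, with 1 higher and a median of -0.85 (adjusted p = 6.86e-12, and adjusted p = 0.482 with an estimated correlation). Insig1 changed by -3.06 ± 0.09 and Hmgcs1, an early enzyme of the pathway, by -2.74 ± 0.08. Each of the 22 ER chaperone and quality-control genes fell, with a median of -0.74 (adjusted p = 4.32e-09, and adjusted p = 0.49 with an estimated correlation). Xbp1, a transcription factor of the unfolded protein response, changed by -2.34 ± 0.09 and Edem1, which acts in ER-associated degradation, by -2.06 ± 0.08. Of 31 integrated stress response genes, 22 fell and 5 rose, with a median of -0.57 (adjusted p = 0.000206, and adjusted p = 0.696 with an estimated correlation). Trib3, a pseudokinase gene activated by ATF4, had the largest fall named, -4.71 ± 0.12, while Ppp1r15a, the stress-induced phosphatase subunit GADD34, rose by 2.31 ± 0.08. Mitotic and cell cycle genes fell in 30 of 42 cases and rose in 5, with a median of -0.40 (adjusted p = 0.000207, and adjusted p = 0.696 with an estimated correlation). The other large falls of protein-coding genes with a mean of at least 10 CPM over the 6 libraries were Scd2, a fatty acid desaturase (-4.31 ± 0.08), Ptprb, a receptor tyrosine phosphatase (-3.96 ± 0.15), Wrb, a receptor for tail-anchored proteins at the ER (-3.91 ± 0.13), and Pik3r2, a regulatory subunit of PI3-kinase (-3.71 ± 0.10). Leaving out control 2 and TCZ 2 gave medians of -0.95 for cholesterol genes, -0.80 for ER chaperones, -0.62 for the integrated stress response and -0.46 for the cell cycle list.

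Mitochondrially encoded transcripts fell in 14 of 15 cases, with mt-Rnr1 higher and a median of -1.31 (adjusted p = 0.00181, and adjusted p = 0.49 with an estimated correlation). Nuclear copies of the mitochondrial genome may take part of their reads. That median was -0.84 without control 2 alone, and -0.84 without control 2 and TCZ 2. Cytosolic ribosomal protein genes, whose pseudogenes can share reads, fell in 39 of 79 cases and rose in 1, with a median of -0.19 (adjusted p = 0.0224, and adjusted p = 0.885 with an estimated correlation). The number that fell was 14 without control 1 (median -0.09), 53 without control 2 (-0.29), 75 without control 2 and TCZ 2 (-0.29) and 75 with a batch term (-0.30), and 19 without TC 1 and 24 without TC 2. Ribosome biogenesis genes rose in 19 of 32 cases and fell in 5 (median 0.40, adjusted p = 0.0221, and adjusted p = 0.825 with an estimated correlation). Contractile and SRF target genes rose in 17 of 29 and fell in 4 (median 0.28, adjusted p = 0.00476, and adjusted p = 0.865 with an estimated correlation). Among spliced noncoding transcripts such as snoRNA hosts, which nonsense-mediated decay degrades during translation, 8 of 16 rose and 3 fell (median 0.23, adjusted p = 0.00181, and adjusted p = 0.45 with an estimated correlation). For p53 targets, 13 of 27 rose and 8 fell (median 0.37, adjusted p = 0.00285, and adjusted p = 0.49 with an estimated correlation). The snoRNA host and p53 calls ended with the replicate block (adjusted p = 0.0801 and 0.0835), with a batch term (0.0838 and 0.109) and without control 2 and TCZ 2 (0.0673 and 0.0977). Without those libraries the medians were 0.37 for ribosome biogenesis, 0.22 for SRF targets, 0.26 for snoRNA hosts and 0.33 for p53 targets; without TC 2 that of p53 targets was 0.23. Scaling by library totals alone gave medians of -0.33 for ribosomal proteins, 0.26 for ribosome biogenesis, 0.13 for SRF targets, 0.09 for snoRNA hosts, 0.23 for p53 targets and 0.06 for necroptosis genes.

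Genes of the TNF receptor and necroptosis pathway moved in both directions, with 18 of 37 higher and 12 lower (median 0.21, adjusted p = 0.0118, and adjusted p = 0.49 with an estimated correlation). That call ended with no low-count filter (adjusted p = 0.074), with the replicate block (adjusted p = 0.194), with a batch term (adjusted p = 0.241) and without control 2 and TCZ 2 (adjusted p = 0.219). Tnfrsf1a, the main TNF receptor gene, fell from 102 ± 1.80 to 60.4 ± 1.82 CPM (log2 -0.75 ± 0.07, adjusted p = 4.96e-09), and the kinase gene Ripk1 changed by -0.78 ± 0.08. Mlkl, which encodes the pore-forming executor of necroptosis (chromosome 8, 111311681 to 111338456, minus strand), rose by 0.50 ± 0.11 from 15.5 ± 0.43 to 21.8 ± 2.71 CPM (adjusted p = 0.000311). Cflar, a caspase-8 regulator, rose by 0.72 ± 0.07. Casp8 (-0.23 ± 0.09, adjusted p = 0.0245) and Ripk3 (-0.19 ± 0.08, adjusted p = 0.0419) lay near the threshold. Both calls were lost with no low-count filter (adjusted p = 0.161 for Casp8 and 0.264 for Ripk3), without control 1 (0.261 and 0.321), without TC 1 (0.135 and 0.187) and without TC 2 (0.0843 and 0.201), and that of Casp8 also with DESeq2 (0.0808) and after thinning (0.0941). The adaptor gene Fadd did not pass (0.07 ± 0.11, adjusted p = 0.578). Of 31 genes of the apoptosis machinery, 9 were higher and 15 lower (median -0.18, adjusted p = 0.726); Pmaip1 and Bid, both proapoptotic, rose by 2.56 and 2.01, and Casp6 changed by -3.21.

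The remaining lists did not pass in TC against control. Counts higher and lower were 10 and 22 of 40 extracellular matrix genes (median -0.32, adjusted p = 0.0824), 6 and 16 of 30 hypoxia and glycolysis genes (-0.23, 0.329), and 6 and 16 of 25 NRF2 and oxidative stress genes (-0.39, 0.472). These 3 lists passed without control 2 and TCZ 2 (adjusted p = 0.00145, 0.00711 and 0.0396), as did nuclear oxidative phosphorylation genes (0.0396), of which 3 of 31 were higher and 6 lower with all 6 libraries (-0.04, 0.479). All 4 passed with a batch term too (0.00243, 0.0117, 0.0438 and 0.0416), matrix and NRF2 genes with no low-count filter (0.00849 and 0.0232), and matrix genes with library totals alone (0.00204) and the replicate block (0.0283). With the batch term 3 oxidative phosphorylation genes were higher and 15 lower (median -0.14), and their median was -0.11 without control 2 and TCZ 2. Autophagy and lysosome genes were higher in 12 of 28 cases and lower in 6 (0.12, 0.245), and heat shock genes in 9 and 8 of 22 (median 0.00 to 2 decimals, adjusted p = 0.348). With library totals alone the median of the autophagy list was below 0. With a batch term 11 of its genes were higher and 10 lower (median 0.07), and its median was 0.05 without control 2 and TCZ 2. Among markers of other cell types, epithelial genes were higher in 6 of 8 cases and lower in 1 (median 2.75, adjusted p = 0.0824), and passed without control 2 and TCZ 2 (0.0396), with a batch term (0.0448), with no low-count filter (0.0229), with the replicate block (0.0362) and after thinning (0.0387). Krt19 went from 15.3 ± 1.84 to 66.6 ± 4.0 CPM and Krt18 from 2.53 ± 0.06 to 10.03 ± 0.61 CPM. Macrophage and leukocyte markers had 1 higher and 1 lower of 14 (median -0.28, adjusted p = 0.617). Endothelial markers had 1 higher, the growth factor receptor gene Kdr, and 2 lower of 7, with a median of -0.61 and mean of -0.41 although the test pointed up (adjusted p = 0.311). Muscle markers had 2 higher and 1 lower of 5, with a median of 0.55, a mean of -0.35 and a test pointing up (adjusted p = 0.869), and neural markers 2 higher and 1 lower of 8, with a median of 0.44, a mean of 0.82 and a test pointing down (adjusted p = 0.976). Adjusted over the list alone, the counts higher and lower became 10 and 15 for apoptosis, 19 and 12 for necroptosis, 14 and 8 for p53, 5 and 23 for the integrated stress response, 1 and 37 for ribosomal proteins, 19 and 6 for ribosome biogenesis, 13 and 6 for autophagy and 7 and 1 for epithelial markers, with no change in the other lists. By fry, which does not compare a list with other genes, ribosomal proteins did not pass (adjusted p = 0.225), while endothelial (0.00887) and epithelial markers (0.00181) did.

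**Figure D1:**
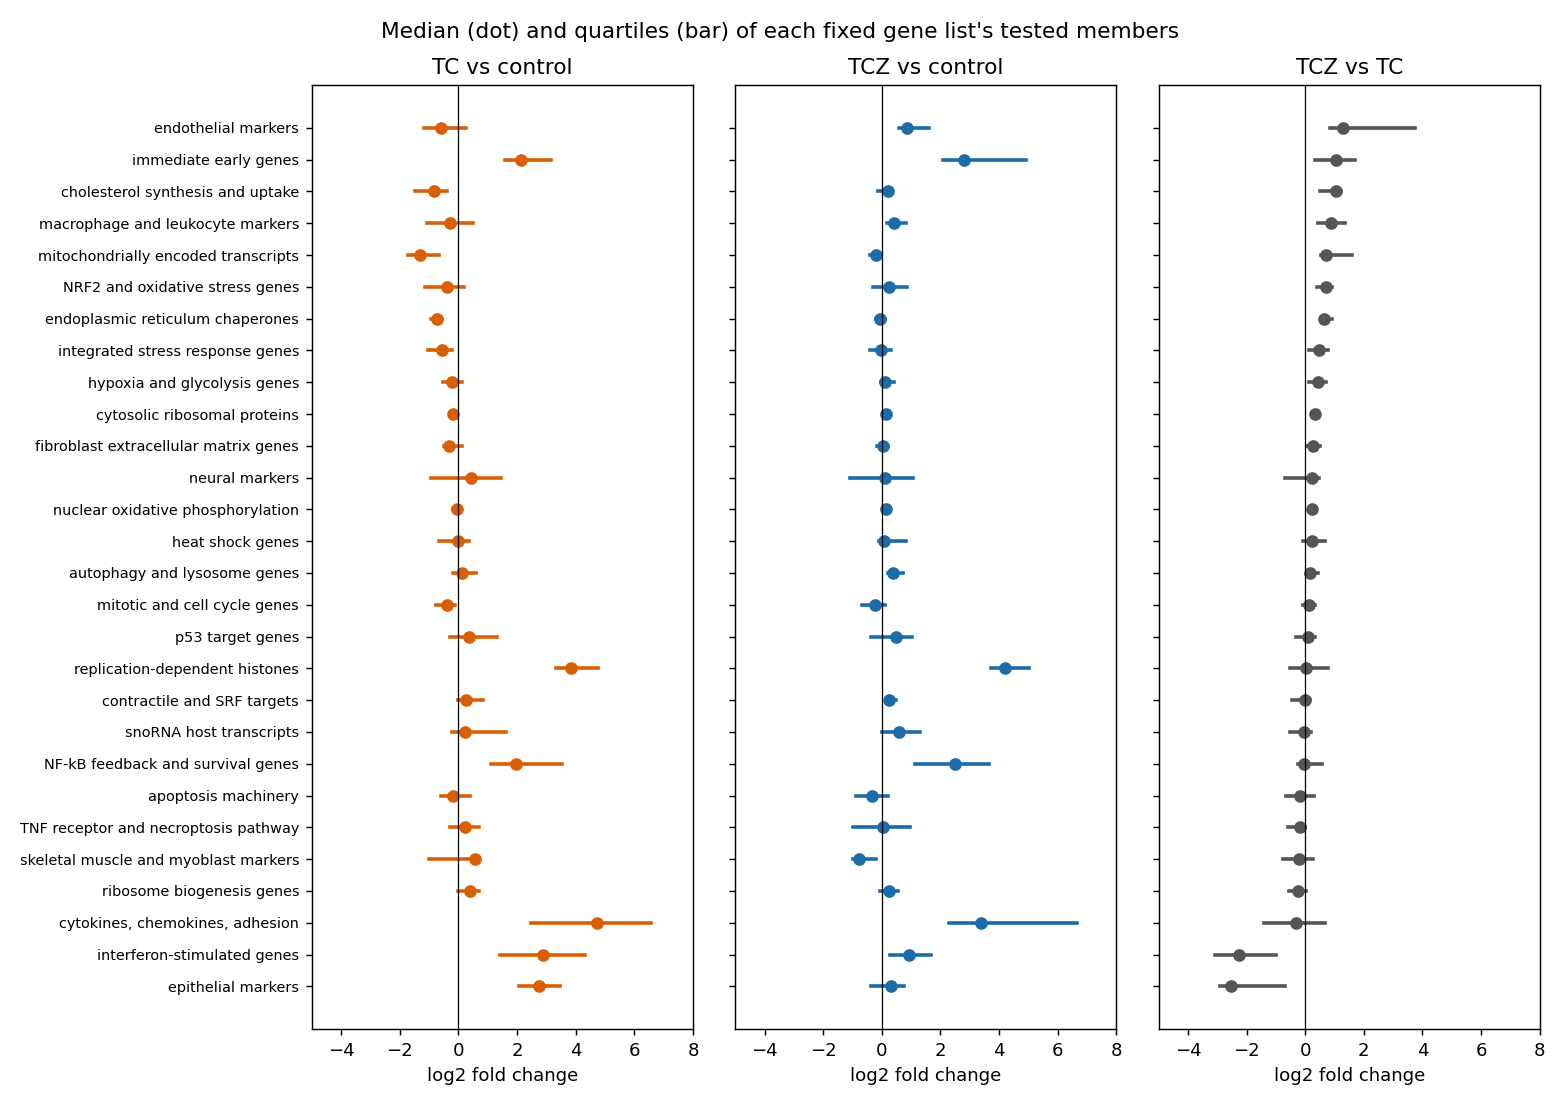
Median (dot) and quartiles (bar) of the log2 fold changes of each fixed list's tested genes, in TC against control, TCZ against control and TCZ against TC. Interferon-stimulated genes sit at 2.88 in TC and 0.92 in TCZ against control and at -2.26 in TCZ against TC, while histones sit at 3.83 and 4.20 against control.

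TCZ was compared with control to ask what TNF-α and cycloheximide changed when caspases were inhibited. Immediate early genes, NF-kB targets, cytokines and histones rose again, autophagy, NRF2 and p53 target genes rose in part, and fewer interferon-stimulated genes passed than in TC. Arc, an immediate early gene best known from neurons (chromosome 15, 74669081 to 74672570, minus strand), rose from 2.50 ± 0.02 to 1997 ± 191 CPM (SD, n = 2), and Cxcl2 from 0.05 ± 0.02 to 562 ± 68.5 CPM. Tnfrsf1a fell to 25.01 ± 0.32 CPM. In all, 11164 of 18563 genes passed, 5851 higher and 5313 lower, and at least 2-fold changes numbered 3403 and 2562. With library totals alone the split was 4556 higher and 7017 lower. With control 2 and TCZ 2 left out, 9796 genes passed, of which 9333 were among the 11164.

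Of 40 immediate early genes, 39 rose and 1 fell, with a median of 2.81 (adjusted p = 4.87e-114, and adjusted p = 0.189 with an estimated correlation). Arc rose by 9.64 ± 0.12 on the log2 scale (adjusted p = 1.53e-23), Atf3 by 8.73 ± 0.11 and Egr4, a zinc finger transcription factor gene, by 11.63 ± 0.19 to 893 ± 105 CPM. Among NF-kB genes 22 of 25 rose and 1 fell, with a median of 2.50 (adjusted p = 3.82e-39, and adjusted p = 0.189 with an estimated correlation). Tnfaip3 rose by 7.97 ± 0.11 to 1458 ± 153 CPM and Gadd45b by 5.99 ± 0.10. Bcl2l1, the antiapoptotic gene of this list that fell, changed by -1.95. Cytokines and adhesion molecules rose in 23 of 29 cases and fell in 3, with a median of 3.38, or 3.10 with 2 genes at their bound (adjusted p = 3.09e-41, and adjusted p = 0.189 with an estimated correlation). Cxcl1 rose by 9.08 ± 0.12, Cxcl2 by 13.35 ± 0.19, and Csf2 was at least 2793-fold higher at 104 ± 9.43 CPM. All 20 histone genes rose, with a median of 4.20 (adjusted p = 2.83e-21, and adjusted p = 0.343 with an estimated correlation), including Hist1h2bc by 4.32 ± 0.09 and Hist1h1c by 3.45 ± 0.09. For immediate early genes, the NF-kB list, cytokines and histones, the medians without control 2 and TCZ 2 were 2.84, 2.59, 3.47 and 4.31.

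Interferon-stimulated genes rose in 26 of 42 cases and fell in 5, with a median of 0.92 (adjusted p = 0.0291, and adjusted p = 0.971 with an estimated correlation). Their call ended after thinning (adjusted p = 0.0691). Cxcl10 rose by 8.22 ± 0.14 and Irf1, a transcription factor gene activated by interferon and TNF, by 3.60 ± 0.10. Autophagy and lysosome genes rose in 23 of 28 cases and fell in 3, with a median of 0.37 (adjusted p = 0.00436, and adjusted p = 0.971 with an estimated correlation), with Sqstm1, an autophagy receptor, at 1.90 ± 0.08 and the proton pump subunit gene Atp6v1h at 1.23 ± 0.07. NRF2 and oxidative stress genes rose in 14 of 25 and fell in 6, with a median of 0.26 (adjusted p = 0.00436, and adjusted p = 0.971 with an estimated correlation), and that median was 0.06 with library totals alone, 0.14 without TCZ 1 and 0.17 without control 2. The NRF2 call ended with no low-count filter (adjusted p = 0.134). The metallothionein genes Mt2 and Mt1 of this list rose by 4.48 ± 0.09 and 3.55 ± 0.09. Among p53 targets 16 of 27 rose and 8 fell, with a median of 0.47 (adjusted p = 0.00663, and adjusted p = 0.814 with an estimated correlation). Btg2, an antiproliferative gene also counted as immediate early, rose by 4.40 ± 0.09 and the kinase gene Plk2 by 2.42 ± 0.08. This call ended with no filter (adjusted p = 0.0565) and without control 2 and TCZ 2 (adjusted p = 0.0726).

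Of snoRNA hosts and other such noncoding transcripts, 11 of 16 rose and 3 fell, with a median of 0.59 (adjusted p = 0.0291, and adjusted p = 0.814 with an estimated correlation), a call that ended with library totals alone (adjusted p = 0.0504) and after thinning (adjusted p = 0.0506). Cell cycle genes fell in 23 of 42 cases and rose in 9, with a median of -0.24 (adjusted p = 0.0387, and adjusted p = 0.971 with an estimated correlation), and this call too ended after thinning (adjusted p = 0.0691). Once control 2 and TCZ 2 were left out, the medians were 0.83 for interferon-stimulated genes, 0.37 for autophagy, 0.29 for NRF2, 0.32 for p53, 0.67 for snoRNA hosts and -0.28 for the cell cycle list. Scaling by library totals alone gave 0.17 for autophagy, 0.27 for p53, 0.39 for snoRNA hosts and -0.44 for the cell cycle list. The other large rises were Fcgr1, with 2 control counts and a ratio of 1681 (counting interval 465 to 13900; log2 13.75 without control 1 and 9.92 without control 2), and Cilp2, a cartilage matrix gene (9.91 ± 0.21). The largest falls of protein-coding genes with a mean of at least 10 CPM over the 6 libraries were Trib2, a pseudokinase gene (-5.0 ± 0.12), Sema6d, a guidance molecule (-4.71 ± 0.14), Armcx4 (-4.31 ± 0.13), Mgat5, a glycan-branching enzyme (-4.29 ± 0.16), and Dhx32, a helicase-like gene (-4.11 ± 0.15).

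In the cell death pathway, Tnfrsf1a changed by -2.03 ± 0.08 (adjusted p = 7.67e-16), Casp8 by -1.06 ± 0.09 to 17.3 ± 1.25 CPM, Mlkl by -0.97 ± 0.12 to 7.92 ± 0.38 CPM and Ripk1 by -0.83 ± 0.08. Ripk3 changed by -0.32 ± 0.08 (adjusted p = 0.00115), Cflar rose by 0.61 ± 0.07, and Fadd did not pass (-0.11 ± 0.11, adjusted p = 0.386), although it did with library totals alone (-0.31, adjusted p = 0.0256). As a list, necroptosis genes had 15 higher and 14 lower of 37 (median 0.03, adjusted p = 0.358), a median that was below 0 with library totals alone, without control 2 and without TCZ 1. The apoptosis machinery had 8 higher and 16 lower of 31 (median -0.34, adjusted p = 0.44). Further lists that did not pass were the integrated stress response (10 higher, 12 lower of 31, median -0.04, adjusted p = 0.703), ER chaperones (4 and 6 of 22, -0.05, 0.34), heat shock genes (9 and 4 of 22, 0.08, 0.156), ribosomal proteins (7 and 0 of 79, 0.14, 0.44), ribosome biogenesis (19 and 6 of 32, 0.25, 0.44), SRF targets (19 and 4 of 29, 0.24, 0.34) and cholesterol genes (13 and 5 of 25, 0.20, 0.729). The same held for hypoxia and glycolysis genes (13 and 4 of 30, 0.11, 0.44), mitochondrial transcripts (2 and 7 of 15, -0.20, 0.895), nuclear oxidative phosphorylation genes (11 and 0 of 31, 0.14, 0.44) and extracellular matrix genes (11 and 8 of 40, median 0.04 with a mean of 0.00 and a test pointing down, 0.895). With library totals alone, the medians of the heat shock, ribosomal protein, hypoxia, oxidative phosphorylation and matrix lists were below 0. Without control 2 and TCZ 2, ribosomal proteins (adjusted p = 8.41e-06, 48 higher and 0 lower), ribosome biogenesis (0.0358), SRF targets (0.00365) and oxidative phosphorylation (0.0174) passed. With no low-count filter SRF targets (0.0451) and endothelial markers (0.0451) did.

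Markers of other cell types in TCZ against control gave 3 higher and 0 lower of 7 endothelial genes (median 0.85, adjusted p = 0.0565). Pecam1, an endothelial and platelet adhesion molecule, was at 0.08 ± 0.08 CPM in control, 0.14 ± 0.06 in TC and 10.8 ± 0.09 in TCZ. Leukocyte markers were higher in 3 and lower in 1 of 14 (median 0.41, adjusted p = 0.657), and the integrin gene Itgam reached 4.74 ± 1.66 CPM. Epithelial markers were higher in 1 and lower in 1 of 8, with a median of 0.32, a mean of 0.52 and a test pointing down (adjusted p = 0.934), and that median was -0.07 without control 2 and TCZ 2. Muscle markers were higher in 0 and lower in 1 of 5 (median -0.79, adjusted p = 0.697), and neural markers in 2 and 2 of 8 (median 0.11, below 0 with library totals alone; adjusted p = 0.889). Adjusted over the list alone, the counts higher and lower became 9 and 16 for apoptosis, 17 and 8 for p53, 4 and 5 for ER chaperones, 0 and 0 for ribosomal proteins, 14 and 7 for NRF2, 7 and 0 for oxidative phosphorylation, 3 and 0 for leukocyte and 3 and 2 for neural markers, with no change in the other lists. The apoptosis (adjusted p = 0.0469), necroptosis (0.0185), heat shock (0.0326), leukocyte (0.0159), endothelial (0.00621) and muscle lists (0.0291) passed by fry.

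**Figure D2:**
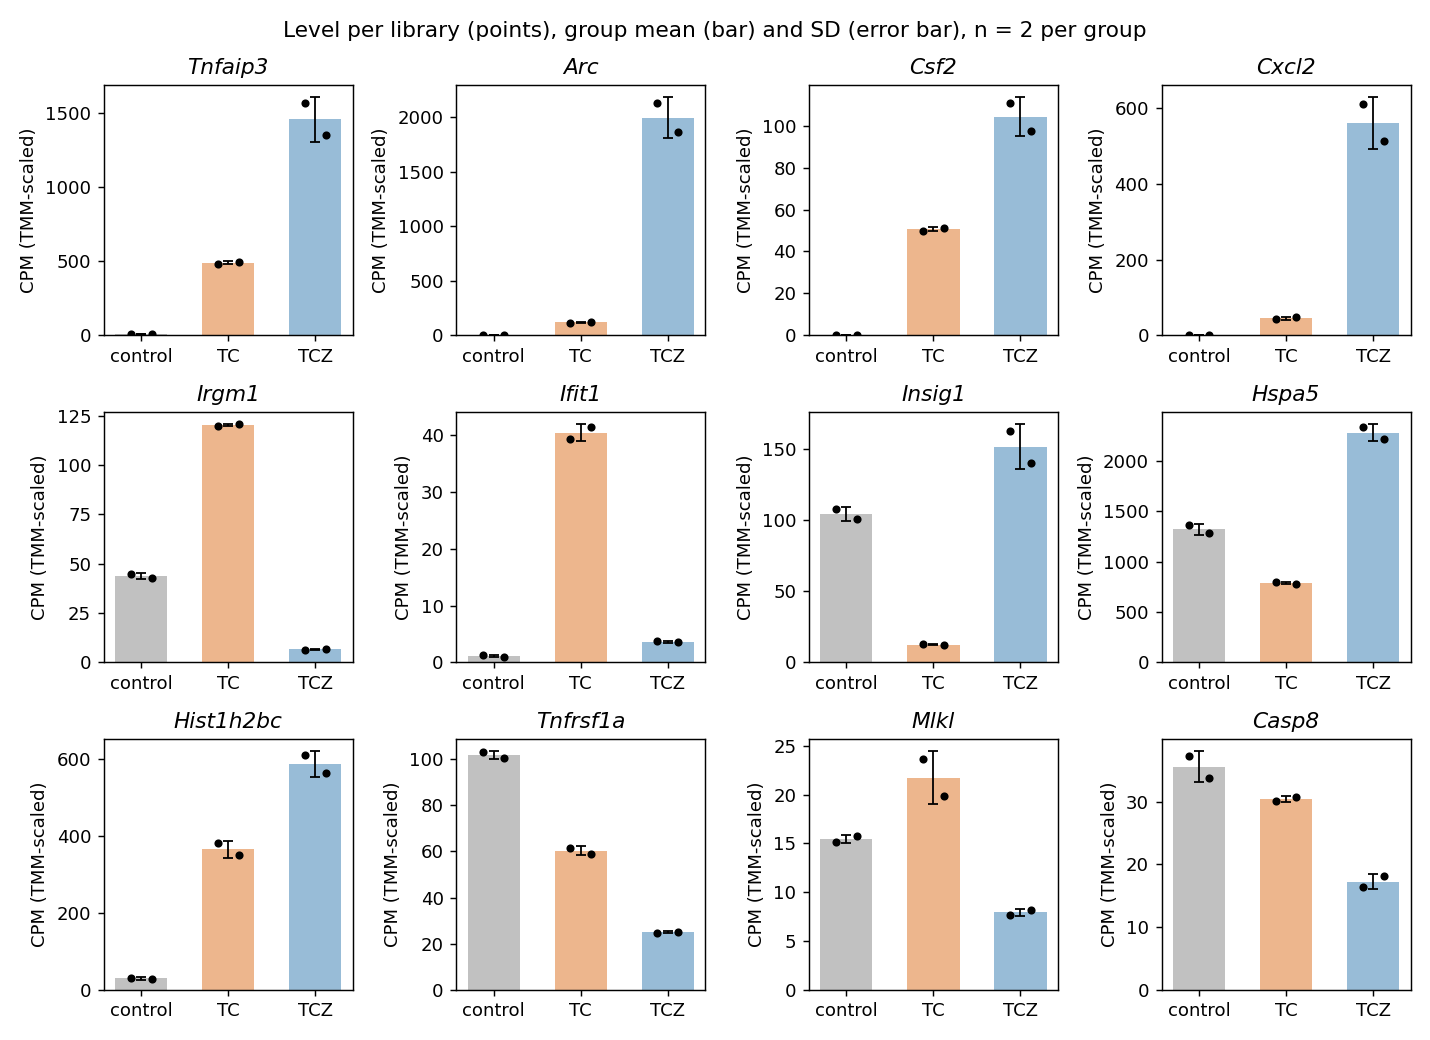
CPM (TMM-scaled) of 12 named genes in each library (points), with group means (bars) and SD (error bars), n = 2 per group; each panel has its own axis from 0. Tnfaip3 and Arc step up from control to TC to TCZ, Irgm1 and Ifit1 peak in TC at 120 and 40.4 CPM, and Insig1 and Hspa5 are lowest in TC.

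TCZ was compared with TC to ask what adding z-VAD-fmk changed. Interferon-stimulated genes were lower in TCZ, while immediate early genes, cholesterol synthesis, ER chaperones, NRF2 targets and mitochondrial transcripts were higher. Irgm1, an interferon-inducible GTPase gene (chromosome 11, 48865245 to 48871454, minus strand), was at 120 ± 0.54 CPM in TC and 6.65 ± 0.42 CPM in TCZ (SD, n = 2), and Rsad2, which encodes the antiviral enzyme viperin, at 31.7 ± 1.07 and 1.84 ± 0.79 CPM. Insig1 was at 12.5 ± 0.45 CPM in TC and 151 ± 16 CPM in TCZ. In all, 10414 of 18563 genes passed, 5235 higher and 5179 lower, and at least 2-fold differences numbered 2149 and 2178. The split with library totals alone was 4837 higher and 5746 lower. Among libraries other than control 2 and TCZ 2, 9679 genes passed, of which 9058 were among the 10414.

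Of 42 interferon-stimulated genes, 37 were lower and 1 higher in TCZ, with a median of -2.26 (adjusted p = 4.23e-26, and adjusted p = 0.0939 with an estimated correlation). Irgm1 differed by -4.19 ± 0.09, Rsad2 by -4.22 ± 0.19 and Parp14, an ADP-ribosyltransferase gene, by -3.49 ± 0.11. Irf1 was the higher one (2.04), and Cxcl10, also a TNF-responsive chemokine gene, did not pass (-0.01, adjusted p = 0.958). Immediate early genes were higher in 32 of 40 cases and lower in 5, with a median of 1.06 (adjusted p = 8.54e-31, and adjusted p = 0.658 with an estimated correlation), with Arc at 4.09 ± 0.08 and the transcription factor gene Egr3 at 2.71 ± 0.08. All 25 cholesterol genes were higher, with a median of 1.05 (adjusted p = 3.98e-22, and adjusted p = 0.658 with an estimated correlation), including Insig1 by 3.60 ± 0.09 and Hmgcs1 by 2.60 ± 0.08. ER chaperones were higher in 20 of 22 cases and lower in 2, with a median of 0.64 (adjusted p = 1.36e-08, and adjusted p = 0.658 with an estimated correlation). Hspa5, the ER chaperone BiP, differed by 1.53 ± 0.07 at 2276 ± 86.1 CPM in TCZ, and Dnajb9 by 1.63 ± 0.08. NRF2 genes were higher in 22 of 25 cases and lower in 2, with a median of 0.70 (adjusted p = 2.94e-08, and adjusted p = 0.658 with an estimated correlation), among them Srxn1, a peroxiredoxin repair enzyme, by 2.04 ± 0.08 and Mt2 by 1.26 ± 0.08.

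Ribosomal protein genes were higher in 69 of 79 cases and lower in 0, with a median of 0.33 (adjusted p = 2.21e-05, and adjusted p = 0.752 with an estimated correlation), such as Rpl36a by 0.57 ± 0.07 and Rplp1 by 0.56 ± 0.08. Without TCZ 1 the numbers were 28 and 1, with a median of 0.19. All 15 mitochondrial transcripts were higher, with a median of 0.70 (adjusted p = 7.58e-05, and adjusted p = 0.658 with an estimated correlation), including mt-Rnr2, a mitochondrial ribosomal RNA, by 1.19 ± 0.07 and CYTB by 0.70 ± 0.07. Integrated stress response genes were higher in 21 of 31 cases and lower in 4, with a median of 0.46 (adjusted p = 2.75e-05, and adjusted p = 0.752 with an estimated correlation), led by Mthfd2, an enzyme of one-carbon metabolism (1.49 ± 0.08), and the amino acid transporter gene Slc7a5 (1.08 ± 0.08). Heat shock genes were higher in 14 of 22 and lower in 2 (median 0.24, adjusted p = 0.00019, and adjusted p = 0.731 with an estimated correlation). Hypoxia and glycolysis genes were higher in 20 of 30 and lower in 3 (median 0.43, adjusted p = 0.011, and adjusted p = 0.752 with an estimated correlation). Autophagy genes were higher in 15 of 28 and lower in 3 (median 0.18, adjusted p = 0.0219, and adjusted p = 0.752 with an estimated correlation), with 9 higher without TC 1 and 8 without TCZ 1. Nuclear oxidative phosphorylation genes were higher in 21 of 31 and lower in 0 (median 0.24, adjusted p = 0.0339, and adjusted p = 0.752 with an estimated correlation), or 7 and 1 without TCZ 1 (median 0.14), 7 and 0 without TC 1 and 11 and 0 without TC 2. Extracellular matrix genes were higher in 23 of 40 and lower in 6 (median 0.27, adjusted p = 0.0446, and adjusted p = 0.752 with an estimated correlation). Without control 2 and TCZ 2 the medians were -2.20 for interferon-stimulated genes, 1.12 for immediate early genes, 1.09 for cholesterol, 0.70 for ER chaperones, 0.75 for NRF2, 0.44 for ribosomal proteins, 0.64 for mitochondrial transcripts, 0.53 for the integrated stress response, 0.34 for heat shock, 0.51 for hypoxia, 0.23 for autophagy, 0.32 for oxidative phosphorylation and 0.33 for matrix genes.

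SRF targets were lower in 13 of 29 cases and higher in 7, with a median of -0.01 and a mean of -0.25 (adjusted p = 0.0468, and adjusted p = 0.752 with an estimated correlation). Their median was above 0 with RLE size factors, DESeq2, a batch term, without TC 2, without TCZ 2 and without control 2 and TCZ 2, and the call ended with a batch term (adjusted p = 0.121), with the replicate block (0.115) and without control 2 and TCZ 2 (0.347). The number higher was 3 without TC 1, without TC 2 or without TCZ 1, 12 without control 2 and TCZ 2 and 13 with a batch term, against 12 to 14 lower in these settings. Tnfrsf1a was lower in TCZ by -1.27 ± 0.08 (adjusted p = 5.61e-12), Mlkl by -1.47 ± 0.11 and Casp8 by -0.83 ± 0.09. Ripk1 (-0.05 ± 0.08, adjusted p = 0.637), Ripk3 (-0.14 ± 0.08, 0.141), Fadd (-0.19 ± 0.11, 0.147) and Cflar (-0.11 ± 0.07, 0.211) did not pass. With library totals alone Ripk3 (adjusted p = 0.00587) and Cflar (0.00672) did, as did Ripk3 without TCZ 1 (0.0353). The value of Ripk1 was above 0 without TC 1 (0.02) and without TCZ 1 (0.02). Necroptosis genes as a list were higher in 4 and lower in 15 of 37 (median -0.18, adjusted p = 0.129), and passed with no low-count filter (adjusted p = 0.00129) and with the replicate block (0.0394). The apoptosis machinery was higher in 8 and lower in 13 of 31 (-0.18, 0.412). The largest rises of protein-coding genes with a mean of at least 10 CPM over the 6 libraries were Ttc21a (7.32 ± 0.23), Sele, the adhesion molecule E-selectin (5.16 ± 0.15), Apobec1, a cytidine deaminase (4.56 ± 0.11), the kinase gene Map3k15 (4.48 ± 0.11) and Mmp25, a membrane metalloprotease (4.45 ± 0.15). Ttc21a lies next to Csrnp1 on the opposite strand, which was at 248 ± 12.6 CPM in TC and 637 ± 49.8 CPM in TCZ. The strand setting is not given in the sources used here, so reads of Csrnp1 were not separated from those of Ttc21a, whose value was 6.60 without TC 1 and 8.79 without TC 2. The largest falls under the same limits, besides Irgm1 and Rsad2, were Scube3, a secreted signalling protein (-4.55 ± 0.10), S1pr1, a sphingosine-1-phosphate receptor (-3.98 ± 0.10), and Bnc1, a zinc finger gene (-3.85 ± 0.17).

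Lists that did not differ between TCZ and TC by the test were NF-kB genes (9 higher and 8 lower of 25, median -0.06 with a mean of 0.03 and a test pointing up, adjusted p = 0.689), cytokines (8 and 15 of 29, -0.32, 0.201), p53 targets (8 and 8 of 27, 0.09, 0.954), ribosome biogenesis (5 and 17 of 32, -0.23, 0.0875), snoRNA hosts (4 and 6 of 16, -0.03, 0.308), cell cycle genes (18 and 7 of 42, 0.12, 0.121) and histones (5 and 5 of 20, 0.04, 0.549). The histone median was below 0 with library totals alone, without TC 1 and without TCZ 1. Ribosome biogenesis passed with library totals alone (adjusted p = 0.0362), with no low-count filter (0.00146) and with the replicate block (0.0291), and cell cycle genes without control 2 and TCZ 2 (adjusted p = 0.0312). In that setting the medians of NF-kB genes, snoRNA hosts and neural markers turned to 0.07, 0.06 and -0.08. Epithelial markers were lower in 5 of 8 cases and higher in 0, with a median of -2.52 (adjusted p = 0.0246, and adjusted p = 0.658 with an estimated correlation); this call ended without control 2 and TCZ 2 (adjusted p = 0.0587). Krt19 and Krt18 were at 13.2 ± 2.79 and 1.40 ± 0.12 CPM in TCZ. Leukocyte markers were higher in 4 and lower in 0 of 14 (median 0.89, adjusted p = 0.131), endothelial markers in 5 and 1 of 7 (1.30, 0.284), muscle markers in 1 and 2 of 5 (-0.23, 0.363) and neural markers in 2 and 2 of 8 (median 0.24 with a mean of -0.01, 0.689); leukocyte (0.0141) and endothelial markers (0.0334) passed with no low-count filter. Adjusted over the list alone, the counts higher and lower became 10 and 8 for NF-kB, 9 and 15 for cytokines, 33 and 5 for immediate early genes, 9 and 14 for apoptosis, 70 and 0 for ribosomal proteins, 24 and 7 for matrix genes, 8 and 13 for SRF targets, 21 and 3 for hypoxia, 22 and 3 for NRF2 and 2 and 0 for leukocyte markers, with no change in the other lists. Fry did not pass ribosomal proteins (adjusted p = 0.0892), hypoxia (0.0519), autophagy (0.0551), oxidative phosphorylation (0.0885), matrix genes (0.0892) and SRF targets (0.0551). It passed cytokines (0.0331), apoptosis (0.0489), necroptosis (0.0198), ribosome biogenesis (0.0256), snoRNA hosts (0.0256), leukocyte (0.00645), endothelial (0.0256) and muscle markers (0.0193).

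The TC and TCZ responses were also set side by side. Of the genes tested, 3855 were higher and 3457 lower than control in both, 7312 in all, and 796 passed in opposite directions. The numbers were 3024 and 4837 with library totals alone. Independent lists of the same sizes would share 1846 and 1548 genes, and 20 simulations of unchanged groups against the same controls shared means of 0.05 and 0.1. No gene was changed in the simulations, so few could be called at all. These means therefore do not show how much the shared controls add where most genes pass. The fold changes correlated at 0.759 across genes, against 0.512 in the simulations, and their covariance was 3.15 against 0.164, a difference of 2.99. Part of the overlap may come from the shared controls, since 2 control libraries cannot be split into separate sets with replicates. Without control 2 and TCZ 2 the shared calls numbered 6451.

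**Figure D3:**
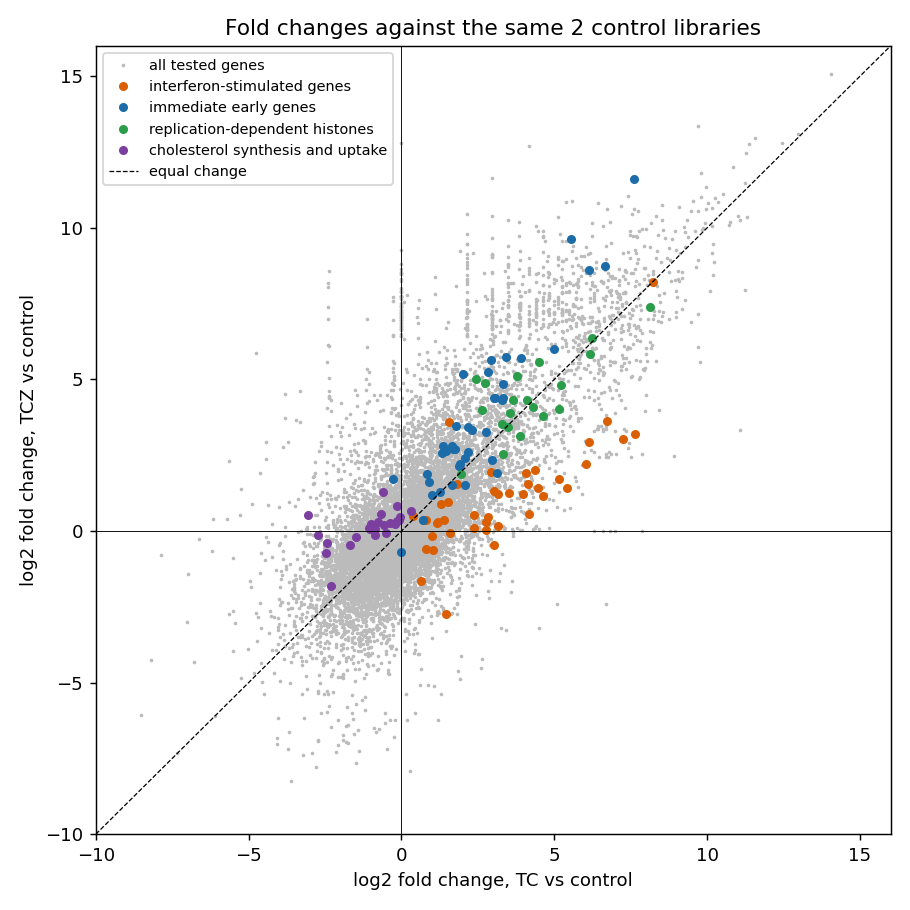
Log2 fold change of each tested gene in TCZ against control (vertical axis) and TC against control (horizontal axis), with the dashed line marking equal change. Interferon-stimulated genes have medians of 0.92 in TCZ and 2.88 in TC, with 37 of 42 lower in TCZ than in TC by the test, and cholesterol genes have medians of 0.20 in TCZ and -0.85 in TC.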

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

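The batch term, leaving out control 2 and TCZ 2, and thinning to equal depth were chosen after the data were seen. Counts of passing genes stayed within 1.5 times the main counts under every alternative except a required change of at least 1 on the log2 scale, which left 5438, 5965 and 4327 genes. Leaving out single libraries gave 9355 to 11662 genes for TC against control, 9423 to 11397 for TCZ against control, 8639 to 10335 for TCZ against TC and 5825 to 6978 shared calls. DESeq2 kept 10295, 10263 and 9268 of the main calls, and thinning kept 10296, 10132 and 9439. Library totals alone turned the direction of 99 calls in TCZ against control. Of the named genes, Ripk3 and Casp8 in TC against control lost their calls in the settings given with their values. Libraries with the same replicate number shared little deviation over all tested genes. The correlations were 0.01 for control with TC, 0.12 for control with TCZ and -0.02 for TC with TCZ, which cannot exclude pairing. With the replicate block 11240, 11166 and 10435 genes passed. List tests were repeated with RLE size factors, library totals, no filter, the block, the batch term, without control 2 and TCZ 2, and after thinning, but not with DESeq2, limma-voom, the filter of 50 counts or only 2 groups; with each single library left out only their counts and medians were recomputed. The cause of the changes that follow was not tested, apart from fewer samples, fewer reads or more tested genes where the setting itself brings them.

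With an estimated correlation the adjusted p in TC against control was 0.112 for NF-kB genes, cytokines and interferon-stimulated genes, 0.197 for immediate early genes, 0.2 for histones, 0.482 for cholesterol, 0.49 for necroptosis, p53, ER chaperones and mitochondrial transcripts, 0.45 for snoRNA hosts, 0.696 for the integrated stress response and cell cycle, 0.825 for ribosome biogenesis, 0.865 for SRF targets and 0.885 for ribosomal proteins. In TCZ against control it was 0.189 for NF-kB genes, cytokines and immediate early genes, 0.343 for histones, 0.814 for p53 and snoRNA hosts, and 0.971 for interferon-stimulated, cell cycle, NRF2 and autophagy genes. In TCZ against TC it was 0.0939 for interferon-stimulated genes, 0.658 for immediate early genes, ER chaperones, cholesterol, NRF2, mitochondrial and epithelial genes, 0.731 for heat shock, and 0.752 for the integrated stress response, ribosomal proteins, matrix, SRF targets, hypoxia, autophagy and oxidative phosphorylation.

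With library totals alone the value of Fadd in TC against control turned to -0.07 (-0.073), matrix genes passed in TC against control (adjusted p = 0.00204), snoRNA hosts did not in TCZ against control (0.0504), and ribosome biogenesis passed in TCZ against TC (0.0362). After thinning, the value of Fadd in TCZ against control turned to 0.004, epithelial markers passed in TC against control (0.0387), and snoRNA hosts (0.0506), interferon-stimulated genes (0.0691) and cell cycle genes (0.0691) did not in TCZ against control. The value of Ripk1 in TCZ against TC ranged from -0.134 to 0.023 over single libraries left out. With no low-count filter, TC against control lost necroptosis (0.074) and gained matrix (0.00849), NRF2 (0.0232) and epithelial genes (0.0229); TCZ against control lost p53 (0.0565) and gained SRF targets (0.0451) and endothelial markers (0.0451), and lost NRF2 (0.134); TCZ against TC gained necroptosis (0.00129), ribosome biogenesis (0.00146), leukocyte (0.0141) and endothelial markers (0.0334).

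With the replicate block, TC against control lost necroptosis (0.194), p53 (0.0835) and snoRNA hosts (0.0801) and gained matrix (0.0283) and epithelial genes (0.0362), and TCZ against TC gained necroptosis (0.0394) and ribosome biogenesis (0.0291) and lost SRF targets (0.115). With the batch term, TC against control lost necroptosis (0.241), p53 (0.109) and snoRNA hosts (0.0838) and gained matrix (0.00243), hypoxia (0.0117), NRF2 (0.0438), oxidative phosphorylation (0.0416) and epithelial genes (0.0448), and TCZ against TC lost SRF targets (0.121). Without control 2 and TCZ 2, TC against control lost necroptosis (0.219), p53 (0.0977) and snoRNA hosts (0.0673) and gained matrix (0.00145), hypoxia (0.00711), NRF2 (0.0396), oxidative phosphorylation (0.0396) and epithelial genes (0.0396). TCZ against control lost p53 (0.0726) and gained ribosomal proteins (8.41e-06), ribosome biogenesis (0.0358), SRF targets (0.00365) and oxidative phosphorylation (0.0174), and TCZ against TC lost SRF targets (0.347) and epithelial markers (0.0587) and gained cell cycle genes (0.0312).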

Other observations

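Genes outside the fixed lists, chosen after their values were seen, moved with the treatments as well. Neat1, a noncoding RNA that builds nuclear paraspeckles, was at 57.8 ± 1.48 CPM in control, 307 ± 8.40 in TC and 64.3 ± 0.41 in TCZ, with a log2 difference of -2.25 ± 0.07 between TCZ and TC (adjusted p = 3.73e-16). The replication-independent histone genes H3f3b and H1f0 rose in TC by 2.02 ± 0.08 and 1.47 ± 0.08 and in TCZ by 3.18 ± 0.08 and 2.86 ± 0.08. Casp4, an inflammatory caspase, rose by 5.26 ± 0.20 in TC and 4.37 ± 0.21 in TCZ. Dnm3os, a noncoding host of microRNAs, went from 51.5 ± 0.91 CPM in control to 18.5 ± 1.11 in TC and 1.02 ± 0.19 in TCZ. Tert, the catalytic subunit of telomerase, went from 7.45 ± 0.30 to 1.09 ± 0.20 and 0.93 ± 0.50 CPM.

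In a scan of 64 families of genes with a shared symbol stem, run after the data were seen, Zfp genes were lower in TCZ. Of 343 tested, mostly zinc finger transcription factors, 218 were lower and 60 higher than control (median -0.76, camera adjusted p = 7.86e-05, and adjusted p = 0.963 with an estimated correlation), and 217 were lower and 30 higher than TC (median -0.71, adjusted p = 3.92e-08, and adjusted p = 0.998 with an estimated correlation). Of 59 histone genes of the Hist family, 58 rose in TC and 57 in TCZ, and none of the 59 fell in either (0 and 0). Xist and Ddx3y, markers of female and male cells, were both present in every library and both higher in TC, at 70.0 ± 1.65 against 41.4 ± 0.17 CPM and 196 ± 5.57 against 101 ± 6.99 CPM.

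Of the tests below, those of small RNAs, S phase, leukocytes, the NF-kB list and Ifnb1 were chosen after results were seen; those of the batch in histones, read-through, overlap and genomic DNA were written before, although 16 of 20 tested olfactory receptor genes had already been seen to rise in TCZ. The first pattern is the rise of replication-dependent histone transcripts, which normally end without a poly(A) tail, in both treatments. Carry-over of RNA without a tail would raise other such RNAs and stays open: over control 1, 8 small RNAs had a median log2 ratio of 0.215 in TC (from -0.395 to 2.5) and 0.509 in TCZ 1, where abundant Rn7s1 and Rn7s2 were at 0.24 and 0.20 but Rn7sk and Rpph1, with 3 and 2 counts in control 1, at 4.08 and 2.80. In TCZ 2, histones lay above control 2 by a median of 3.77, while the small RNAs moved both ways in this pair. Rn7s1, with 4 counts in TCZ 2, changed by -7.389, Rn7s2 by -9.632, Rny3 by -2.217, Rnu73b by -0.831 and Rnu1a1 by -0.497. Rn7sk rose by 2.043, Rpph1 by 1.852 and Rnu7 by 0.996, from 8, 3 and 6 counts in control 2. A larger share of cells in S phase is argued against as the whole cause. The 17 replication genes had medians of -0.356 in TC (95% interval -0.869 to -0.06) and 0.121 in TCZ (-0.258 to 0.444). A library batch is argued against too. With a batch term the smaller of the histone medians, that of TC, was 3.693. In TCZ against control that term could hardly change the histone median, since control 2 and TCZ 2 are 1 library of each group. Without both libraries the histone median in TCZ was 4.31. Polyadenylation or longer life of histone transcripts under translation block remains a hypothesis that may hold but was not tested, as no sample received cycloheximide alone.

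The second pattern is the lower level of interferon-stimulated genes in TCZ than in TC, with a median of -2.26 (95% interval -2.74 to -1.62) and -2.24 with a batch term. Leukocytes in the TC cultures would make their markers lower in TCZ, but these had a median of 0.888 (0.18 to 1.57). Epithelial markers did move as the interferon list did (median -2.52, 5 of 8 lower and 0 higher). With 8 genes their interval of -4.24 to 1.72 is the range from the lowest to the highest member. Its upper end is Krt7, which did not pass, at 0.031 ± 0.015 CPM in TC and 0.103 ± 0.029 CPM in TCZ. A share of epithelial cells was not tested. A weaker rise of NF-kB targets as a whole is argued against by the NF-kB list, whose median was -0.057 (-0.18 to 0.36, SD of members 1.09). Immediate early genes were higher in 32 of 40 cases. Whether the response to TNF itself was weaker stays open, since TNF-α and cycloheximide were always given together. For a part of the TNF targets it stays open too, as cytokines were lower in 15 and higher in 8 of 29 cases (median -0.32). More interferon beta transcript in TC could not be excluded or shown, with Ifnb1 counts of 16 and 7 in TC and 12 and 0 in TCZ (exact conditional p = 0.394, two-sided, which covers counting error only and not the spread between libraries). An effect of caspase inhibition on interferon signalling, including a later death of the cells or a different sampling state, stays open as untested.

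The last pattern is the appearance of genes that were under 1 CPM in control: 2213 rose at least 4-fold in TCZ and 1667 in TC, 1202 of them in both. The low-count filter can keep a gene low in control when another group is higher. The share that rose was therefore not read as an effect. Of all 6189 genes tested under 1 CPM in control, 303 fell at least 4-fold in TCZ and 242 in TC. Noncoding genes made up 49.7% of the 2213 and 55.2% of the 6189. With a batch term 98.1% of the 2213 kept the rise. Control 2 and TCZ 2 are 1 library of each group compared, so that term could hardly change this comparison. Fewer of the 2213 kept the rise without control 2 and TCZ 2, where 1 control and 1 TCZ library remained. Read-through from an induced upstream gene on the same strand and within 20 kb is argued against as the whole cause. For 12.4% the nearest upstream gene on the same strand within 20 kb was induced. That share was 1.85% among 2000 sampled low genes that were not themselves induced at least 4-fold in TCZ. Reads of an overlapping induced gene, found for 13.6%, are argued against as the whole cause too. Together, 31.5% had an induced nearest neighbour on the same strand within 20 kb or an overlap, and the others had neither. Neighbours on the opposite strand that do not overlap were not counted. Read-through from these stays open, since the strand setting is not given in the sources used here. For a part of the pattern, read-through stays open, with 218 genes having such a neighbour only upstream and 195 only downstream (exact binomial p = 0.279, two-sided). This test cannot decide it, since adjacent genes that both belong to the pattern add to the upstream and the downstream count alike. Genomic DNA stays open. Of 1141 olfactory receptor genes, 3.94% had a read in both TCZ libraries, 1.23% in both control and 2.89% in both TC libraries. Per library the shares were 6.66% and 6.57% in TCZ, 5% and 4.12% in TC, and 1.84% and 1.58% in control. The TCZ share lay below the bound set beforehand, but a small amount of DNA could stay under that bound too. No biological explanation was tested.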
